A study of Homo sapiens with 6 samples.

How the data were processed

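The samples were 6 RNA-seq libraries from cells differentiated from a human induced pluripotent stem cell line, 3 without K-3 (Control) and 3 with K-3 at 2 µM from day 6 to day 8. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, messenger RNA was purified with poly-T beads, fragmented, copied with random hexamers and sequenced as paired-end reads. The protocol text describes both a directional and a non-directional library and does not say which was used, so antisense and overlapping genes cannot be told apart here. Of the 85 tested genes that the naming rule took, 11 share exon bases with another tested gene, and 2 of these, DDIT3 and RPS6, share at least 10% of them.

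The authors deposited FPKM values for every gene and library, with gene lengths and positions. HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the build GRCh38 are named in the submitters' processing notes, without their order or settings. All 58735 gene IDs and positions in the table equal those of GENCODE release 29. Y-linked genes, XIST and TSIX were left out of every step, which left 58215 genes. Each FPKM times the gene's length is a whole multiple of a step that is constant within a library. In these steps 100% of the values above 0 came out within 1e-06 of a whole number, so whole fragments per gene could be computed. The steps correspond to library sizes that lie within 0.35% of median-of-ratios size factors times the mean total, so the FPKM carry a scaling of that kind between libraries. The recovered totals were 35334645 to 38773637 fragments in Control and 41839266 to 50199369 with K-3. A gene of 1 kb with 3 fragments has 0.0591 to 0.0834 FPKM at these depths; such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

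FPKM are not counts, so genes were tested with limma 3.58.1 (lmFit and eBayes with a trend, in R 4.3.3) on log2(FPKM + 1), K-3 against Control, two-sided. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12968 in all, of which 11172 are protein-coding. Adjusted p-values are Benjamini-Hochberg values over these genes, and the threshold was 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so only the model across genes was used.

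The 44 gene lists, with 705 entries, covered pathways, pancreatic stages and other cell types. All but 2 entries matched a gene of the table. Lists with at least 5 tested genes (32) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The directional fry test of limma was planned beside camera and adjusted over the same lists. Its adjusted p was 0.0081 for G2/M and ATF4 response. It was 0.035 for pancreatic progenitor, FOXO, and FGF and ERK targets, 0.04 for G1/S and hedgehog, and 0.049 for cholesterol synthesis. Other lists past camera's preset test did not pass fry. These were retinoic acid and endocrine progenitor (0.079), TGF-beta (0.15), ribosomal proteins (0.17), unfolded protein response (0.18), mitochondrial-encoded (0.47) and BMP (0.51). In camera with the estimated correlation 0 lists passed, the smallest adjusted p was 0.36, and 2 lists, ATF4 response and G2/M, had an unadjusted p under 0.05. Among the lists that passed with the preset 0.01, the estimate ranged from -0.08 (FGF and ERK targets) to 0.83 (mitochondrial-encoded). It was 0.46 for G2/M and 0.24 for ATF4 response. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls among protein-coding genes past the threshold whose groups did not overlap, 12 pancreatic progenitor and endocrine genes whatever their result, and up to 4 members with the smallest p of each list past its test; a few of these genes are not reported here.

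The fits were tested on simulated fragments drawn for the real genes at the real means and library sizes. In these, 200 genes with a real mean of at least 1 FPKM were changed. The filter was then applied to the simulated values, which left 12973 genes tested. A changed gene that dropped below the filter counted as not recovered, so the rates below mix the filter with the power of the test. For K-3 against Control, 54% of the genes changed 1.25-fold, 64% of those changed 1.5-fold, 90% of those changed 2-fold and 88% of those changed 4-fold were recovered, with 4 unchanged genes called. In a second simulation over 12959 genes, camera called 5 of 5 lists changed 1.25-fold and 0 of 40 unchanged lists, with the preset and with the estimated correlation. In both simulations genes varied independently of each other, which real genes need not do. Simulated genes of similar level also shared the same dispersion, the spread beyond counting noise, which real genes do not. These rates may therefore be too favourable.

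Each alternative changed 1 choice, except the replicate block with scaling, which changed both. They were pseudocounts of 0.1 and 2, minimum means of 0.1 and 5 FPKM or none, TPM, median of log-ratios and quantile scaling, rescaling without mitochondrial-encoded genes, eBayes without a trend or with a robust trend, array quality weights, a replicate block with and without median of log-ratios scaling, protein-coding genes only, limma voom on the recovered fragments, and each library left out. Fragments thinned to equal depth and a correction for GC content and length were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.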

Results

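The series measured messenger RNA in cultures differentiated towards pancreatic progenitors from a human induced pluripotent stem cell line, a reprogrammed line that can form every tissue of the body. Cells were kept from day 6 to day 8 in a differentiation step that the labels call S3, either without K-3 (Control, n = 3 libraries) or with K-3 at 2 µM (n = 3). K-3 is a code name in the labels, and nothing further about it is stated there. The stated question was how K-3 changes the differentiation of these cells, read from their whole transcriptome at the progenitor stage. Values were the authors' deposited FPKM per gene, which are fragment counts scaled for gene length and library size.

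The Control libraries held 38773637, 37807532 and 35334645 fragments assigned to genes, and the K-3 libraries held 50199369, 42973088 and 41839266, so every K-3 library was deeper than every Control library. Nothing in the labels says that the 3 libraries of a group came from separate differentiations, so the p-values measure the spread between these libraries, which may be technical. Across the tested genes, Pearson's r of log2(FPKM + 1) lay between 0.990 and 0.992 for pairs of Control libraries, between 0.992 and 0.994 for pairs of K-3 libraries and between 0.982 and 0.991 for pairs from different groups. The chi-square per degree of freedom of the fragments in a pair ranged from 8.3 to 43.3, so no pair agreed within sampling noise. The first principal component held 48.1% of the variance, with Control libraries at -1.93, -11.34 and -17.2 and K-3 libraries at 7.49, 9.5 and 13.48.

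With K-3, 6 of 13 tested genes of the amino acid stress response controlled by the transcription factor ATF4 fell, and 18 of 20 genes of the G2 and M phases of the cell cycle rose. CHAC1, a glutathione-degrading enzyme induced by ATF4, fell from 2.57 ± 0.24 to 0.333 ± 0.1 FPKM (SD, n = 3 per group; log2 fold change -1.42, SE 0.09, adjusted p = 0.00733). MTHFD2, an enzyme of mitochondrial one-carbon metabolism, fell from 11.5 ± 1.7 to 4.78 ± 0.44 FPKM (log2 fold change -1.11, SE 0.10, adjusted p = 0.0169). BIRC5, which encodes the mitotic protein survivin, rose from 14.4 ± 0.8 to 20.9 ± 1.1 FPKM (log2 fold change 0.51, SE 0.05, adjusted p = 0.0182). PDX1, the homeobox factor that marks pancreatic fate, had 14.3 ± 3.2 FPKM in Control and 22.2 ± 1.2 with K-3, with a log2 fold change of 0.62 and an adjusted p of 0.0634, so it did not pass the test.

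Of 12968 genes tested with limma on log2(FPKM + 1), 152 were higher and 118 lower with K-3 at an adjusted p under 0.05 (Benjamini-Hochberg, two-sided). The protein-coding genes among them numbered 140 higher and 95 lower. At an unadjusted p under 0.05 there were 1518 higher and 1343 lower. The 3 K-3 values lay on one side of the 3 Control values in 27.4% of the tested genes, where chance gives 10% on average over splits of the libraries. Genes vary together, so the share in a single split can lie far from 10%, and the shares of other splits were not computed. The median log2 fold change of the higher genes was 0.36 and that of the lower genes -0.41. No gene passed with a rise of at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes; limma voom on fragments recovered from the FPKM gave 23, and 8 genes rose that far at an unadjusted p under 0.05. The 7 genes that fell at least 2-fold were CHAC1, MTHFD2, SLC7A11, the long non-coding RNA gene FLJ22447 and the short features RNU6-925P, AP000553.7 and RN7SL481P. Those 3 features are copies or pseudogenes whose fragments can belong to related sequences, so their values are uncertain; these and FLJ22447 were named after their values were seen. The counts depended on single libraries, also through the smaller number left: without Control replicate 1 they were 259 higher and 440 lower, without Control replicate 2 they were 275 and 229, without Control replicate 3 they were 1 and 10, without K-3 replicate 1 they were 0 and 5, without K-3 replicate 2 they were 0 and 0, and without K-3 replicate 3 they were 0 and 3. Rescaling the libraries without mitochondrial-encoded genes turned the split to 117 higher and 152 lower, and testing protein-coding genes only gave 402 higher and 285 lower.

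**Figure D1:**
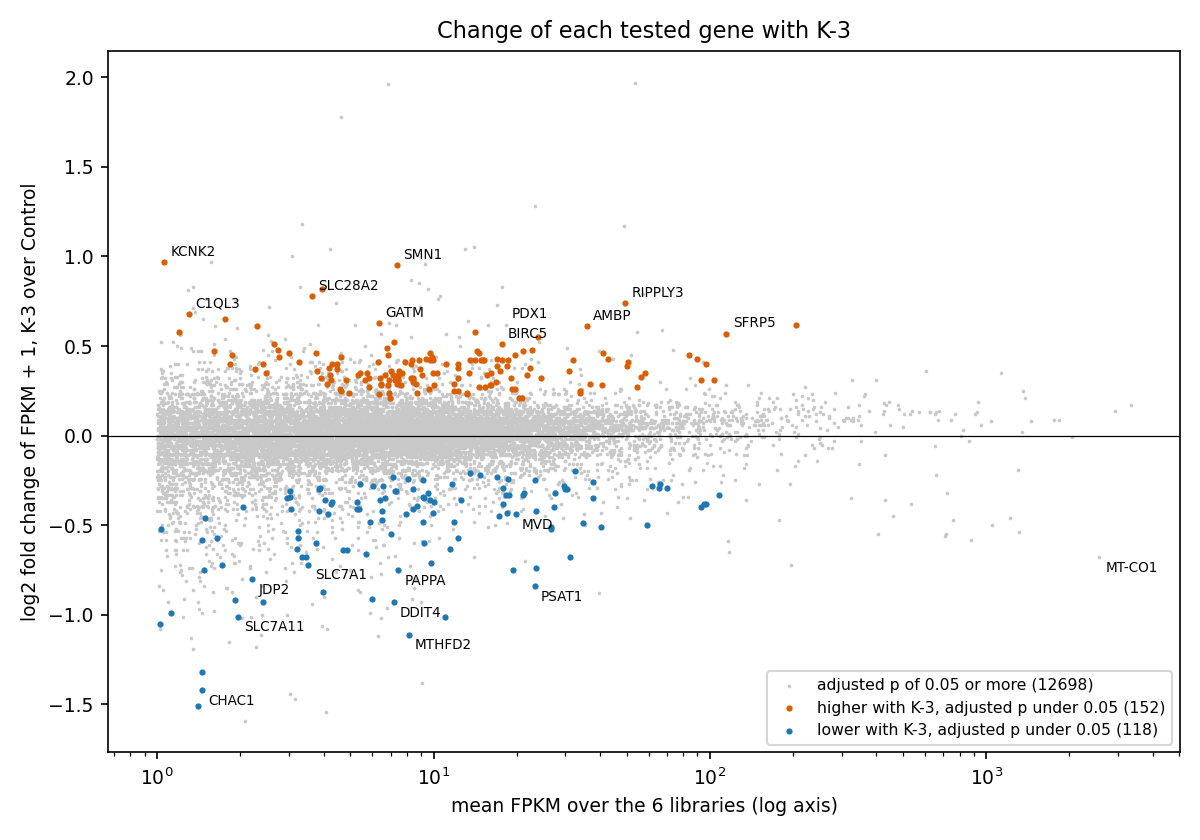
Each point is 1 of 12968 tested genes, with its mean FPKM over the 6 libraries on a log axis and its log2 fold change of FPKM + 1, K-3 over Control, on the vertical axis. The 152 genes higher with K-3 (orange) and the 118 lower (blue) had an adjusted p under 0.05; CHAC1 lies at -1.42, MTHFD2 at -1.11 and KCNK2 at 0.97, while PDX1 did not pass the test.

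Among the largest rises of protein-coding genes past the threshold, KCNK2, a potassium channel, rose from 0.413 ± 0.34 to 1.71 ± 0.19 FPKM (log2 fold change 0.97, SE 0.17, adjusted p = 0.0428). Its Control mean lay below the minimum of 1 FPKM, so it reached the test only through its K-3 values. KCNK2 was still tested in 3 of the 6 fits with a library left out, and passed in 1. LRRN4, a leucine-rich repeat membrane protein, rose by 0.82 on the log2 scale, SLC28A2, a nucleoside transporter, by 0.78, and RIPPLY3, a transcriptional repressor, by 0.74, from 37 ± 6.5 to 61.9 ± 1.8 FPKM. C1QL3 (0.68), the calcium channel subunit gene CACNG6 (0.65), GATM, an enzyme of creatine synthesis (0.63), and AMBP, the precursor of a plasma microglobulin (0.61), also rose. COL9A2, a collagen gene, and CTNND2, which encodes delta-catenin, both rose by 0.58. SFRP5, a secreted Wnt-binding protein of the foregut, rose from 92.4 ± 11 to 137 ± 3.9 FPKM (log2 fold change 0.57, adjusted p = 0.0321). SMN1 rose from 4.8 ± 1.6 to 9.98 ± 1.2 FPKM (log2 fold change 0.95, adjusted p = 0.0499), but its near-identical copy SMN2 stood at 3.29 ± 0.23 and 2.98 ± 0.31, and fragments can be split between the pair, so this value is uncertain. The sum of both copies was 8.09 ± 1.7 FPKM in Control and 13 ± 1.5 with K-3.

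Besides members of the ATF4 list, the largest falls included genes of several kinds. JDP2, a repressor of AP-1 transcription factors, fell from 3.08 ± 0.055 to 1.34 ± 0.063 FPKM (log2 fold change -0.80, SE 0.05, adjusted p = 0.00733). LRRC32, which encodes a cell surface docking protein for latent TGF-beta, fell by 0.87 on the log2 scale, PAPPA, a protease of insulin-like growth factor binding proteins, by 0.75, and DNAJC15, a mitochondrial co-chaperone, by 0.75. ANKRD1, a common target of the YAP coactivator, fell by 0.74 from 29.7 ± 2 to 17.4 ± 2.4 FPKM. SLC7A1, a transporter of cationic amino acids, and ADM2, a peptide hormone of the calcitonin family, both fell by 0.72. Of the 36 genes that the naming rule took and that passed the test, 6 lost their call without Control replicate 1, 3 without Control replicate 2 and 29 without Control replicate 3. Of the 35 of them still tested, 32 lost it without K-3 replicate 1, 35 without K-3 replicate 2 and 32 without K-3 replicate 3, while all kept their direction in each of these fits.

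The genome positions of the leading genes in build GRCh38 are as follows. CHAC1 (ENSG00000128965) spans chromosome 15 from 40952962 to 40956519 on the + strand, and MTHFD2 (ENSG00000065911) spans chromosome 2 from 74198562 to 74217565 on the + strand. BIRC5 (ENSG00000089685) spans chromosome 17 from 78214186 to 78225636 on the + strand, KCNK2 (ENSG00000082482) spans chromosome 1 from 215005775 to 215237093 on the + strand, and PDX1 (ENSG00000139515) spans chromosome 13 from 27920020 to 27926231 on the + strand. All 5 are protein-coding genes, and the values cover their annotated exons as 1 total per gene.

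The ATF4 response list was lower with K-3 (median log2 fold change -0.49 over 13 tested members; camera with a preset correlation of 0.01, adjusted p = 2.7e-09; adjusted p = 0.36 with an estimated correlation). Of the 13 members 6 fell, 0 rose and 7 did not pass, and 9 fell when adjusted over the list alone. Besides CHAC1 and MTHFD2, the members that fell were SLC7A11, the cystine transporter (2.98 ± 0.65 to 0.953 ± 0.05 FPKM), DDIT4, an inhibitor of mTORC1 signalling (9.71 ± 0.59 to 4.62 ± 0.52), PSAT1, an enzyme of serine synthesis (30.2 ± 3.4 to 16.3 ± 0.97), and SESN2, a stress-induced sestrin (11.3 ± 1.3 to 7.12 ± 0.46). Their log2 fold changes were -1.01, -0.93, -0.84 and -0.60. ATF3 (-0.49, adjusted p = 0.0575) and SHMT2 (-0.31, adjusted p = 0.0547) missed the threshold, and PHGDH (0.06), ATF5 (0.03) and TRIB3 (-0.05) lay near 0; these 5 genes and SESN2 were named after their values were seen. ATF5 shares 21.2% of its exon bases with NUP62 on the opposite strand, so its value is uncertain. The list's mean level relative to the average of all libraries was 0.32, 0.19 and 0.34 in the Control libraries and -0.26, -0.28 and -0.30 in the K-3 libraries.

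The unfolded protein response list was lower by a smaller amount (median log2 fold change -0.10 over 15 members, camera adjusted p = 0.0011; adjusted p = 0.56 with an estimated correlation). DDIT3, the stress-induced factor CHOP, fell and the other 14 did not pass; its level went from 8.55 ± 1.3 to 5.48 ± 0.36 FPKM (log2 fold change -0.55, adjusted p = 0.0389), and 2 members fell when adjusted over the list alone. DDIT3 shares 27.2% of its exon bases with MARS on the opposite strand, which was also lower, and strand use in the counting is not given in the sources used here. HERPUD1 (-0.26, adjusted p = 0.0504), XBP1 (-0.20) and HYOU1 (-0.19) did not pass. The list's median was -0.05 without Control replicate 1 and -0.06 without K-3 replicate 1, and the Control libraries ranged over 0.16 in its mean level, where the groups differed by 0.13.

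The cholesterol synthesis list was lower with K-3 (median log2 fold change -0.14, 19 of 19 members with a negative value; camera adjusted p = 5.7e-08; adjusted p = 0.36 with an estimated correlation). MVD, mevalonate diphosphate decarboxylase, fell from 23 ± 1.2 to 16.7 ± 1 FPKM (log2 fold change -0.44, adjusted p = 0.0253). HMGCS1, an early enzyme of the mevalonate pathway, fell from 108 ± 4.2 to 82.8 ± 4.4 FPKM (-0.38), and LSS, lanosterol synthase, from 23.7 ± 1.6 to 18.7 ± 0.92 (-0.32). The other 16 members did not pass, among them STARD4 (-0.30, adjusted p = 0.0604), and 9 fell when adjusted over the list alone.

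The G2/M cell cycle list was higher with K-3 (median log2 fold change 0.40; camera adjusted p = 6.9e-21; adjusted p = 0.36 with an estimated correlation). Of its 20 members, 18 rose and 0 fell, and 20 rose when adjusted over the list alone. AURKB, a kinase of the chromosomal passenger complex, rose from 11.9 ± 0.63 to 16.8 ± 0.53 FPKM (log2 fold change 0.47, SE 0.05, adjusted p = 0.0177). BUB1, a spindle checkpoint kinase, rose by 0.42 and CCNB2, a mitotic cyclin, by 0.39. MKI67 (0.38, adjusted p = 0.0516) and CENPF (0.32, adjusted p = 0.0534), named as the exceptions after their values were seen, did not pass. The list's mean level was -0.18, -0.13 and -0.26 in the Control libraries and 0.19 in each K-3 library.

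The G1/S cell cycle list was also higher (median log2 fold change 0.19 over 17 members, camera adjusted p = 4.8e-06; adjusted p = 0.36 with an estimated correlation). Of these members 1 rose over all genes tested, CDC45, a replication helicase factor, from 1.44 ± 0.063 to 2.22 ± 0.23 FPKM, and 11 rose when adjusted over the list alone. CDT1 (0.24), RRM2 (0.31) and PCNA (0.22) had adjusted p-values of 0.0604, 0.0604 and 0.0687. The ribosomal protein list had a median of 0.13 (camera adjusted p = 0.00022; adjusted p = 0.71 with an estimated correlation), and 0 of its 20 members passed. RPLP1 (0.23), RPS6 (0.19) and RPS19 (0.17) were among the members with the smallest p-values. The Control libraries ranged over 0.17 in the list's mean level, where the groups differed by 0.14.

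**Figure D2:**
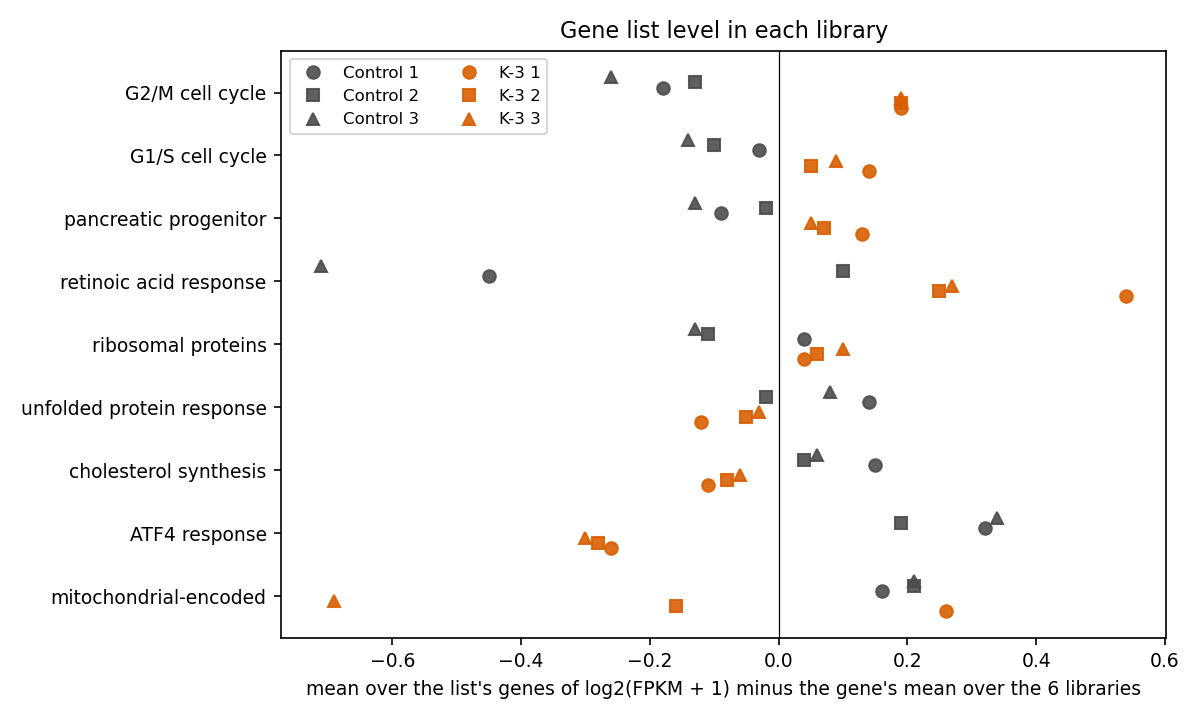
The horizontal axis gives, for 9 gene lists, the mean over the list's genes of log2(FPKM + 1) minus each gene's mean over the 6 libraries; grey symbols are Control and orange symbols K-3 libraries, with a symbol shape per replicate number. G2/M levels lie between -0.26 and -0.13 in Control and at 0.19 with K-3, ATF4 response levels between 0.19 and 0.34 in Control and between -0.30 and -0.26 with K-3, while the retinoic acid level of Control replicate 2 (0.10) lies near the K-3 libraries.

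The pancreatic progenitor list was higher with K-3 as a set (median log2 fold change 0.17 over 13 tested members, camera adjusted p = 0.014; adjusted p = 0.36 with an estimated correlation). None of its members passed over all genes tested, while 6 were higher and 1 lower when adjusted over the list alone. Next to PDX1, SOX9, a factor of multipotent pancreatic progenitors, had 3.65 ± 0.44 FPKM in Control and 5.13 ± 0.86 with K-3 (log2 fold change 0.39, adjusted p = 0.105), and NKX2-2 had 0.827 ± 0.072 and 1.4 ± 0.18 (0.39, adjusted p = 0.0664). GATA4 (0.21, adjusted p = 0.0974), FOXA2 (0.17), MNX1 (0.15) and GATA6 (0.11) did not pass either, nor did HHEX (-0.05), ONECUT1 (-0.12) and PROX1 (-0.32). NKX6-1, another member of the pancreatic progenitor list, had 0 fragments in all 6 libraries. At 3 fragments per library this allows up to 0.019 to 0.027 FPKM, a limit that covers counting error only. PTF1A had 0.0338 ± 0.045 FPKM in Control and 0 with K-3, from 6 and 0 fragments in all. NEUROG3, the trigger of endocrine fate, had 0.0261 ± 0.012 and 0.00477 ± 0.0083, from 4 and 1 fragments. Both lay below the minimum mean and were not tested, and so few fragments show no difference between the groups. The list lost its call without Control replicate 1 (adjusted p = 0.0507) and with a minimum mean of 5 FPKM (median 0.11, adjusted p = 0.129). Its mean level was -0.09, -0.02 and -0.13 in Control replicates 1, 2 and 3, a range of 0.11 where the groups differed by 0.16, and Control replicate 2 lay nearest to K-3, as it did for PDX1. Genes of other lists, named after their values were seen, were higher alongside it without passing: the intestinal factor CDX2 (7.68 ± 2.9 to 13.4 ± 0.84 FPKM, log2 fold change 0.78, adjusted p = 0.0928), HOXB2 (0.96, adjusted p = 0.0606) and VIM, a filament gene of mesenchyme (0.79, adjusted p = 0.118), which shares 12.4% of its exon bases with VIM-AS1 on the opposite strand and is uncertain.

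The endocrine progenitor list, which shares NKX2-2, had a median of 0.11 over 5 tested members (camera adjusted p = 0.047; adjusted p = 0.49 with an estimated correlation). ISL1 (0.40, adjusted p = 0.0802) and RFX6 (0.11) did not pass, and 2 members were higher when adjusted over the list alone. Its call was lost without Control replicate 1 (adjusted p = 0.18), Control replicate 3 (0.082), K-3 replicate 1 (0.11) or K-3 replicate 2 (0.052), and its median was 0.19 without Control replicate 2 and 0.07 without Control replicate 3. The call was also lost at equal depth (adjusted p = 0.0515), with the GC and length correction (0.0797), with array quality weights (0.0704) and by voom (0.0511). The Control libraries ranged over 0.15 in its mean level, where the groups differed by 0.20.

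The retinoic acid response list was higher (median log2 fold change 0.46 and mean 0.71 over 7 tested members, camera adjusted p = 0.0017; adjusted p = 0.36 with an estimated correlation). None of these members passed over all genes tested and 5 were higher when adjusted over the list alone. DHRS3, a retinaldehyde reductase, had 0.52, CRABP1, a retinoic acid binding protein, 0.46 and RARB, a retinoic acid receptor, 0.43 on the log2 scale. The Control libraries differed among themselves: CYP26A1, the enzyme that breaks down retinoic acid, named after its values were seen, had 12.3, 62.4 and 8.29 FPKM in Control replicates 1, 2 and 3 and 110, 61.8 and 66.4 with K-3.

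**Figure D3:**
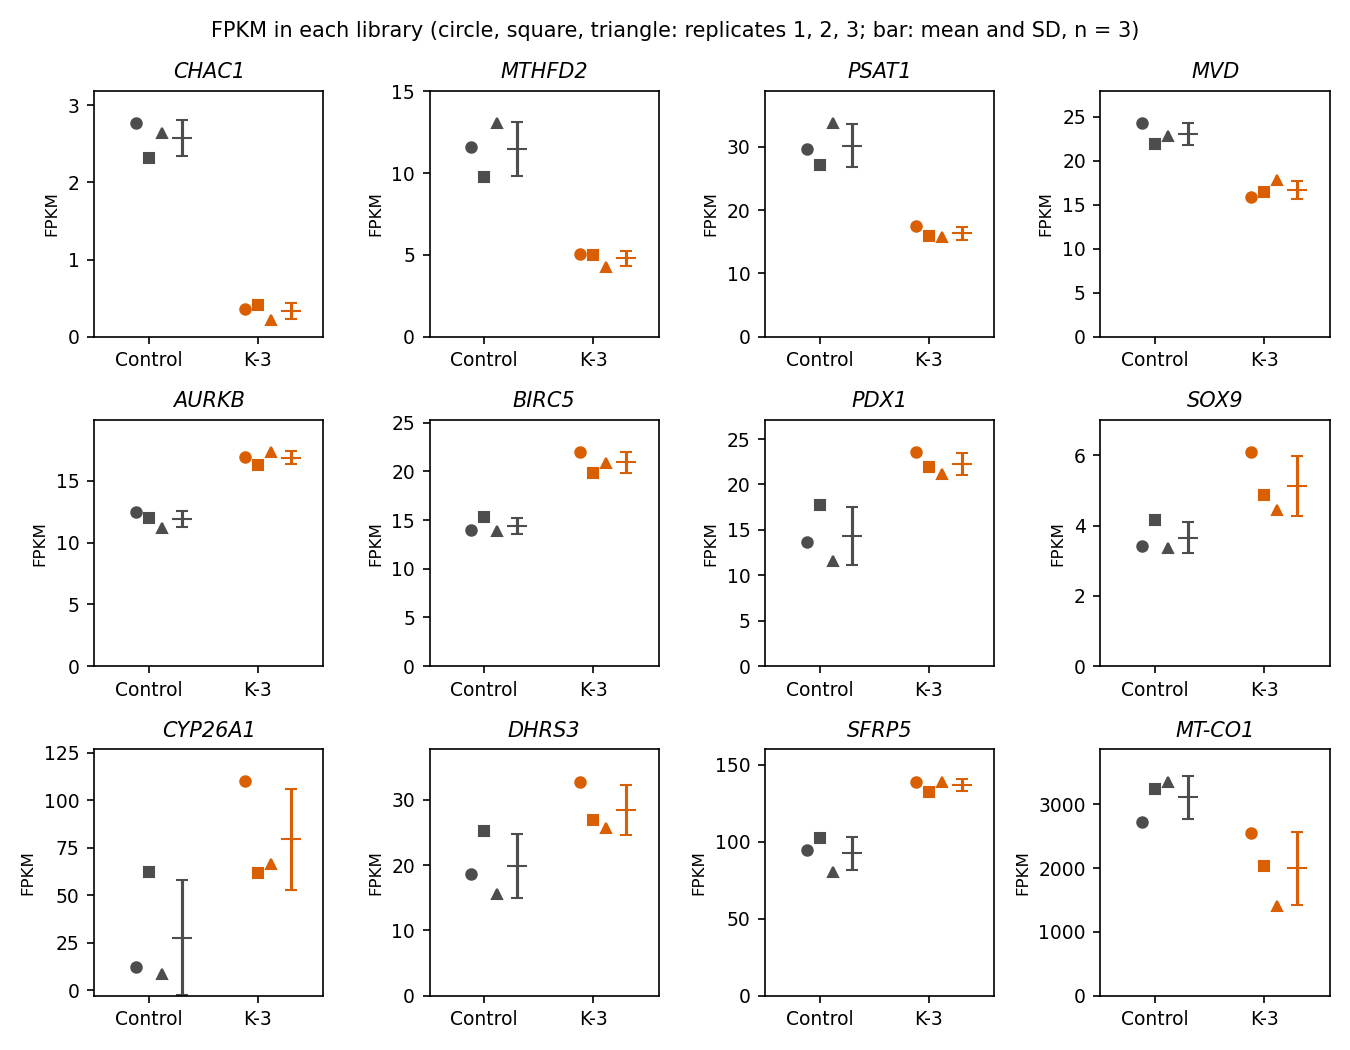
FPKM of 12 genes in each library on linear axes, Control in grey and K-3 in orange; circles, squares and triangles are replicates 1, 2 and 3, and the bar beside them is the mean with its SD (n = 3). CHAC1, MTHFD2, PSAT1, MVD, AURKB, BIRC5 and SFRP5 passed the test, while for CYP26A1 Control replicate 2 (62.4 FPKM) lies above K-3 replicate 2 (61.8 FPKM).

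Signalling lists differed by small amounts. The FGF and ERK target list had a median of 0.11 over 10 members (camera adjusted p = 0.042; adjusted p = 0.36 with an estimated correlation). DUSP6, a phosphatase that acts on ERK, rose from 6.55 ± 0.23 to 8.35 ± 0.32 FPKM (log2 fold change 0.31, adjusted p = 0.0293), SPRY2, a feedback inhibitor of receptor signalling, rose by 0.24 (adjusted p = 0.0497), and 4 members were higher and 1 lower when adjusted over the list alone. SPRED2 (0.20) and DUSP4 (-0.30) did not pass. The list's call was lost without Control replicate 1 (adjusted p = 0.16) or K-3 replicate 3 (0.061), and with TPM (0.053), equal depth (0.0515), the GC and length correction (0.0654), array quality weights (0.0847) or a minimum mean of 0.1 FPKM (0.0895) or 5 FPKM (0.0769).

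The TGF-beta and activin target list had a median of -0.07 over 11 members (camera adjusted p = 0.042; adjusted p = 0.56 with an estimated correlation), and 3 members were lower when adjusted over the list alone. SKIL, a feedback inhibitor of SMAD signalling, fell from 19.7 ± 1.1 to 15.9 ± 0.36 FPKM (log2 fold change -0.29, adjusted p = 0.0375), while NODAL (-0.60, adjusted p = 0.0752) and COL4A1 (-0.59, adjusted p = 0.0667) did not pass. This call was lost without Control replicate 1 (adjusted p = 0.11), K-3 replicate 1 (0.12) or K-3 replicate 2 (0.056), at equal depth (0.0506), with a minimum mean of 0.1 FPKM (median 0.00, adjusted p = 0.652) and with no filter (median 0.01, adjusted p = 0.785). The BMP target list had a median of -0.14 over 11 members with 0 passing (camera adjusted p = 0.043; adjusted p = 0.75 with an estimated correlation; 0 when adjusted over the list alone). SMAD6 (-0.27), SMAD7 (-0.21) and ID2 (-0.19) were below 0 and MSX2 (0.18) above. That call was lost without Control replicate 1 (median -0.09, adjusted p = 0.32), Control replicate 3 (0.082), K-3 replicate 1 (0.24) or K-3 replicate 2 (0.053), with a minimum mean of 0.1 FPKM (0.193) and with no filter (median -0.09, adjusted p = 0.307). The Control libraries ranged over 0.25 in the BMP list's mean level and over 0.14 in the TGF-beta list's, where the groups differed by 0.11 and 0.14.

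The list of FOXO targets and PI3K feedback genes had a median of 0.11 over 15 members with 0 passing and 2 higher when adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.36 with an estimated correlation). TRIB2 (0.26), SESN3 (0.26), TXNIP (0.21) and IRS1 (-0.19) had the smallest p-values in it. Its call was lost without Control replicate 1 (adjusted p = 0.13), Control replicate 3 (0.062), K-3 replicate 1 (0.064) or K-3 replicate 3 (0.059), and its median was 0.07 without K-3 replicate 2. It was also lost with array quality weights (0.0682) and with a minimum mean of 5 FPKM (0.143). The hedgehog pathway list had a median of 0.12 over 8 members with 0 passing, also when adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.36 with an estimated correlation). GAS1 (0.18), IHH (0.16), SMO (0.15) and GLI2 (0.11) led it, and the call was lost without Control replicate 1 (adjusted p = 0.15), Control replicate 2 (0.052), K-3 replicate 2 (0.091) or K-3 replicate 3 (0.087), and with array quality weights (0.0539).

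The mitochondrial-encoded list was lower with K-3 (median log2 fold change -0.47 over 13 genes, camera adjusted p = 0.0036; adjusted p = 0.74 with an estimated correlation), with 0 genes passing, also when adjusted over the list alone. MT-CO1, a subunit of cytochrome c oxidase, had 3110 ± 340 FPKM in Control and 2000 ± 570 with K-3 (-0.68, adjusted p = 0.135). MT-ND4L (-0.58), MT-CYB (-0.56) and MT-CO3 (-0.50) were also below 0. The K-3 libraries differed in this measure: mitochondrial genes took 1.74%, 1.35% and 0.991% of the fragments in K-3 replicates 1, 2 and 3, against 1.64% to 1.78% in Control. Without K-3 replicate 3 the list's median was -0.21 and its call was lost (adjusted p = 0.0613), and without K-3 replicate 1 the median was -0.71.

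Lists for other cell types and for other stress responses did not pass. The hepatic list had a median of -0.03 (camera adjusted p = 0.35), the duct list -0.09 (0.58), the mesenchyme list 0.06 (0.58), the pluripotency list 0.02 (0.76), the definitive endoderm list 0.01 (0.94) and the foregut and gut tube list 0.01 (0.97). The YAP and TEAD list had -0.04 (0.066), the heat shock list 0.04 (0.16), the SRF and actin list -0.05 (0.21), the Notch list -0.12 (0.57), the lysosome list 0.02 (0.6) and the NF-kB list -0.03 (0.63). The p53 target list had 0.05 (0.71), the immediate early list 0.06 (0.72), the glycolysis and hypoxia list -0.01 (0.74), the WNT target list 0.03 (0.74) and the NRF2 list 0.04 (0.8). Of the tested members of these 17 lists 0 rose and 6 fell: APOB (-0.50, adjusted p = 0.0182) and TBX3 (-0.33, adjusted p = 0.0401) of the hepatic list, TPM1 (-0.20, adjusted p = 0.0468) of the SRF and actin list, all named after their values were seen, and ANKRD1, SESN2 and SLC7A11, given above. APOB, TBX3 and TPM1 lost their call without Control replicate 3 and without each K-3 library, and TPM1 also without Control replicate 2. In the pluripotency, NRF2, definitive endoderm and foregut lists the median or the mean had a sign opposite to the test's direction. The other 12 lists, among them islet hormones, acinar, intestine, stomach and lung, neural, endothelial and blood, and muscle markers, had fewer than 5 tested genes each, and 0 of those genes passed.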

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

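The tests at equal depth and with a GC and length correction were chosen after the results were seen; the other alternatives were fixed before. All 85 tested genes taken by the naming rule, 31 of the 33 other tested genes named in the text and the 15 gene lists past their test kept their direction under every alternative in which they were tested. The exceptions were near 0: ATF5 (0.03) had -0.01 with the GC and length correction, and TRIB3 (-0.05) had 0.01 without Control replicate 1, the highest of a range down to -0.09 over its alternatives; the cause was not tested. The list of TGF-beta and activin targets had medians of 0.00 and 0.01 with a minimum mean of 0.1 FPKM and with no filter, where its test remained on the lower side and its call was lost. With a minimum mean of 0.1 FPKM 43 of 21649 tested genes passed and with 5 FPKM 406 of 7549, against 270 of 12968.

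The counts of genes higher and lower with K-3, 152 and 118, moved by over 1.5 times in at least 1 direction under several alternatives, where the cause was not tested unless stated. They were 21 and 22 with a minimum mean of 0.1 FPKM, 0 and 0 with no filter, and 80 and 63 by eBayes without a trend. They were 1091 and 963 with array quality weights, 402 and 285 with protein-coding genes only, 412 and 398 by limma voom, and 243 and 186 with the GC and length correction. With a minimum mean of 5 FPKM 237 genes were higher, and with quantile scaling 185 were lower. With no filter, limma gave 1902 higher and 2263 lower at an unadjusted p under 0.05 among 35411 genes.

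Genes changed at least 2-fold, 0 higher and 7 lower, numbered 3 and 14 with a pseudocount of 0.1, 1 lower with a pseudocount of 2, and 0 lower with no filter. They numbered 2 and 4 with a minimum mean of 5 FPKM, 2 higher with quantile scaling, 11 and 30 with array quality weights, 3 and 3 with protein-coding genes only, 23 and 24 by limma voom, and 3 higher with the GC and length correction. With 1 library left out, fewer libraries remained, and genes higher ranged from 0 to 275 (1050 at an unadjusted p under 0.05 without K-3 replicate 2, where 0 passed), genes lower from 0 to 440, genes at least 2-fold higher from 0 to 21 and genes at least 2-fold lower from 0 to 43.

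Same-numbered Control and K-3 libraries deviated from their group means with correlations across genes of -0.36, -0.03 and -0.11, so the numbers do not pair the libraries. With the replicate number as a block, 0 genes were higher and 0 lower, and 0 passed at 2-fold, also with median of log-ratios scaling; at an unadjusted p under 0.05 limma gave 1121 and 1011 with the block. Of the 15 lists past their test, 1, the hedgehog pathway, lost its call with the block (adjusted p = 0.057) and with the block and scaling (0.0586), where its adjusted p over all alternatives ranged from 0.00786 to 0.363. This fit estimates more terms from the same 6 libraries, and no Control library correlated best with its own number.

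The 9 lists higher and 6 lists lower with K-3 became 0 and 0 with an estimated correlation, and 4 lists were higher with a minimum mean of 5 FPKM. The pancreatic progenitor median went from 0.17 to 0.11 with that minimum, where its call was lost, and with no filter it was 0.10. With no filter the medians were also smaller for the lists of endocrine progenitors (0.04), retinoic acid (0.19), hedgehog (0.06), FGF and ERK targets (0.06), BMP targets (-0.09) and ATF4 response (-0.32), and the endocrine median was 0.07 without mitochondrial-encoded genes. Of the 15 lists, 3 lost their call at equal depth, 2 with the GC and length correction, 4 with array quality weights, 2 with no filter, 3 with a minimum mean of 0.1 FPKM, 1 with TPM and 1 by voom; with 5 FPKM 3 lost it and the endocrine and hedgehog lists had fewer than 5 tested genes. With 1 library left out, lists higher ranged from 4 to 8 and lists lower from 4 to 6. Over its 25 alternatives the adjusted p ranged from 2.45e-11 to 0.363 for the ATF4 response list, from 8.93e-32 to 0.363 for the G2/M list and from 1.13e-10 to 0.363 for the cholesterol synthesis list, where the estimated correlation gave the highest value.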

Other observations

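The comparisons of gene families, of control libraries with each other and of cytosolic with mitochondrial tRNA synthetases were tests chosen after the results were seen. The tests of depth and of GC content and length were also chosen after the main results were seen, though written before their own results. The test of other splits was written before its results. With K-3, 6 of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, fell and 0 rose: AARS (-0.35), GARS (-0.42), TARS (-0.43), MARS, YARS and CARS (-0.42). As a family they were lower by camera over 15 families (adjusted p = 0.00055; adjusted p = 0.61 with an estimated correlation), and none of the 16 mitochondrial ones passed. ATF4 itself, named like the other genes of this part after its values were seen, fell from 110 ± 5.6 to 84.3 ± 0.41 FPKM (log2 fold change -0.38, adjusted p = 0.0253). Among 17 amino acid transporters, SLC7A7, SLC7A1 and SLC7A11 fell and 0 rose (adjusted p = 6.9e-06; 0.17 with an estimated correlation); SLC7A7 had 14.9 ± 0.94 FPKM in Control and 9.7 ± 0.4 with K-3.

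Of 37 kinesin motor genes, 8 rose and 1, KIFC2, fell (adjusted p = 0.016; 0.16 with an estimated correlation). KIFC1, a spindle motor, rose from 16.5 ± 1.5 to 22.8 ± 0.58 FPKM and KIF11 from 14.3 ± 0.37 to 17.7 ± 0.39. KIFC2 shares 17.8% of its exon bases with FOXH1 on the opposite strand, and NCAPG 33.1% with LCORL, so their values are uncertain. The condensin genes NCAPD2 and NCAPG rose among 6 (adjusted p = 0.00055; 0.16 with an estimated correlation). The 20 centromere protein genes were higher as a family, with a median of 0.19 (adjusted p = 6.9e-06; 0.16 with an estimated correlation), and none of them passed alone. The medians of the tRNA synthetase, transporter, condensin and centromere families kept their sign under TPM, median of log-ratios and quantile scaling and without mitochondrial-encoded genes, where the kinesin median went from 0.03 to 0.00. The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. In each of the 3 counts, 1 split, the real one, gave a count as large: 270 genes against at most 0 in the other splits, 7 genes changed at least 2-fold against at most 0, and 15 gene lists against at most 13. At the preset correlation, however, camera called 3 to 13 lists in every other split, where 0 genes passed. The preset test thus called lists readily where Control and K-3 libraries were mixed.

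The ATF4 response list was lower with K-3, with a median of -0.49. A trend on GC content and length is argued against as the whole cause, since the median was -0.52 after its removal. At equal depth the median was -0.51. Thinning keeps each gene's expected FPKM, however, so a median near the original was fixed in advance. It decides nothing on depth or on other differences that go with the deeper K-3 libraries. The range over the Control libraries was 0.27 of the difference between the groups, but it does not measure variation between cultures, since the labels do not say that the libraries came from separate ones. Cytosolic tRNA synthetases, many of them known ATF4 targets outside the list, differed from mitochondrial ones by -0.18 in mean log2 fold change (two-sided permutation test across genes with 100000 resamples, p = 0.0014; camera adjusted p = 0.61 for the cytosolic family with an estimated correlation), which decides nothing on the output of ATF4, since the permutation treats genes as independent and they were chosen after their values had been seen. A response of ATF4 targets to K-3 and a difference in culture or handling that follows the groups both stay open.

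The G2/M list was higher with K-3, with a median of 0.40. After the GC and length correction it was 0.37, which argues against that trend as the whole cause. It was 0.40 at equal depth, where thinning again kept the expected FPKM and so cannot decide on depth or on what else goes with it. The range over the Control libraries was 0.35 of the difference between the groups, which likewise leaves variation between cultures open. More cells in mitosis with K-3 may be a candidate explanation, but it was not tested, since no count of mitotic cells was analysed here. A difference in density or growth phase between the cultures stays open, because no measure of either was analysed here.

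The retinoic acid list was higher with K-3, with a median of 0.46. It had 0.44 after the GC and length correction, which argues against that trend as the whole cause. At equal depth it had 0.42, but thinning keeps the expected FPKM and so cannot decide on depth or on what else goes with it. The range over the Control libraries, however, was 1.16 times the difference between the groups, with Control replicate 2 at 0.10 and the lowest K-3 library at 0.25. Variation between libraries along the same axis may therefore account for this difference, and a response to K-3 stays open as well.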
